A study of Mus musculus with 6 samples.

How the data were processed

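Kidneys of C57BL/6 mice aged 2 months were sequenced, 3 on a standard diet and 3 on an adenine-enriched diet. Per the labels' protocols, total RNA was extracted from whole kidneys, libraries were made from 1 μg of RNA with the TruSeq RNA kit using random hexamers, and 100 bp paired-end reads were taken on an Illumina HiSeq2500. The submitters' processing notes name bcl2fastq 2.0, TopHat and Cufflinks 2.1.1 with the mouse builds mm10 and GRCm38. The TopHat version and the gene annotation are not given in the sources used here. The authors deposited 1 table of FPKM values for these 6 samples, with 40993 genes by Ensembl identifier, symbol and position. Each column was assigned to its sample by the diet and number in its name. Of the identifiers, 97.7% were found in GENCODE release M21, which was used for gene types, and 76.0% of these have the same start and end there. Positions are given as in the deposited table. A table of young and old mice was not used, since its 6 value columns belong to samples outside the sample list. Neither table holds authors' fold changes or p-values.

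FPKM keep no counts, so depth was estimated from the steps of low values. In genes with 1 annotated transcript longer than 2000 bp and FPKM below 0.3, 65.4% to 72.8% of values at 1 to 3 steps lay within 0.15 of a whole number of fragments. The depths in the report follow from these steps with a nominal fragment of 200 bp and are approximate; intervals from them would cover counting error only. Whole fragments were not recovered for nearly all genes, so no count test was run. Genes spanning less than 300 bp, 6722 in the table, carry extreme values, up to 5000000 FPKM, and took 90.1% of the summed FPKM in standard 2 against 11.2% to 26.3% elsewhere.

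The comparison was fitted with limma 3.58.1 in R 4.3.3 (linear model on the diet, moderated variance with an intensity trend, two-sided) on log2(FPKM + 1) for the 15431 genes with a mean of at least 0.5 FPKM over the 6 samples. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 changes on this scale understate the change of genes with low FPKM; folds are ratios of mean FPKM. Where several entries of the table carried a listed symbol, the entry with the highest mean was used. The trend gives very abundant genes a wide expected spread, which bears on Umod and a few genes like it. In data simulated on these 15431 genes, the same code called 62 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, all in the right direction, with 13 false calls. The simulated genes varied independently and had no shift common to a library. The simulation therefore does not cover errors from correlated genes or from scaling. It also changed far fewer genes than the comparison called, and the Benjamini-Hochberg cut-off depends on that share. Its detection rates need not hold for the real comparison.

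Before the data were examined, 37 gene lists were fixed, 28 of kidney and injury biology and 9 checks of other tissue, handling, sex and reference genes. They hold 541 entries, of which 536 were in the table. Each list was described by its members past the threshold, over all genes and over the list alone, and the 33 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, with an estimated correlation beside it, and by fry, with adjustment over the lists. No list kept its camera call with an estimated correlation. The rule for named genes was also set then: (a) 20 genes of kidney injury, function, inflammation and adenine handling; (b) the 8 largest rises and 8 largest falls among changed genes whose groups did not overlap and whose mean reached 5 FPKM in the higher group; (c) up to 2 rises and 2 falls of each list, or the gene with the smallest p where none passed. Other genes are named where a count is 5 or less, or in the closing part, and were chosen after their values were seen. Some genes that these rules select, and a test that used one of them, are not reported here.

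Samples share replicate numbers across the diets. Deviations from the group means correlated at 0.257, 0.143 and 0.181 between samples with the same number and at -0.187 to 0.038 between samples with different numbers. The numbers were therefore taken to pair the samples. The pairing comes from the data, since no label states it. With 3 samples per diet few matchings exist, so equal numbers can match best by chance. Deviations also cancel within a diet, so positive values for some pairs push the others down. The correlations therefore cannot establish a pairing. The model without the block had been set as the main one, and the value with the block is given where it changes a call. Alternatives were the pseudocount (0.1 and 0.5), the filter (none, or a mean of 5 FPKM), median-of-ratios, quantile and top-gene rescaling (without the 50 most abundant genes), the variance prior, the block, stricter thresholds and the omission of each library. Chosen after seeing the data were the omission of genes under 300 bp, protein-coding genes only, and the block together with median-of-ratios scaling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.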

Results

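Whole kidneys of 2-month-old C57BL/6 mice were profiled by RNA sequencing after a standard diet or an adenine-enriched diet, with 3 samples in each group. Adenine in excess of what the body salvages is turned into a poorly soluble product, and feeding it is a common way of injuring the kidney in rodents. The libraries are called standard 1 to 3 and adenine 1 to 3 here. Levels are FPKM, fragments scaled for transcript length and library depth, and every ± is an SD over the 3 samples of a group. Depth, estimated from the spacing of the lowest FPKM values, was 20.3, 17.6 and 16.8 M fragments in standard 1 to 3 and 22.4, 23.7 and 17.5 M in adenine 1 to 3. At the lowest of these depths 3 fragments correspond to 0.089 FPKM for a transcript of 2 kb, so differences below that level were not detectable. The labels do not say that the samples are separate animals, so the p-values measure the spread between these samples.

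The comparison asks which transcripts of the kidney differ between mice on the 2 diets. On the adenine-enriched diet 16 of 17 tubular injury, 21 of 21 extracellular matrix, 17 of 17 macrophage and 16 of 17 proliferation genes rose, and 11 of 22 proximal tubule and 11 of 19 oxidative phosphorylation genes fell. The set test camera placed the first 4 of these lists above other genes and the last 2 below, but no list call held with an estimated correlation (adjusted p = 0.503 or higher), and the set test fry called none of the lists that camera placed lower. Of 15431 genes tested, 5637 changed (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05), 4581 upward and 1056 downward. At least 2-fold changes on the log2(FPKM + 1) scale were found for 1729 genes, 1541 upward and 188 downward, against 1049 and 499 after median-of-ratios scaling and 782 and 378 with quantile normalization. The split depended on scaling: the median of all tested genes lay 0.25 log2 units higher in the adenine group, and 81.3% of the changed genes rose. After median-of-ratios scaling, which takes out that shift, 4942 genes changed, 2598 up and 2344 down (52.6% up), and with quantile normalization 4377 changed, 48.9% of them upward. Of the 5637 genes, 3654 were also called after median-of-ratios scaling, all 3654 with the same sign. Counts of rising and falling genes after that scaling are therefore given for the lists below. Leaving out 1 library gave 2920, 2949 and 2796 changed genes without standard 1, 2 and 3, and 3617, 2124 and 7047 without adenine 1, 2 and 3.

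**Figure D1:**
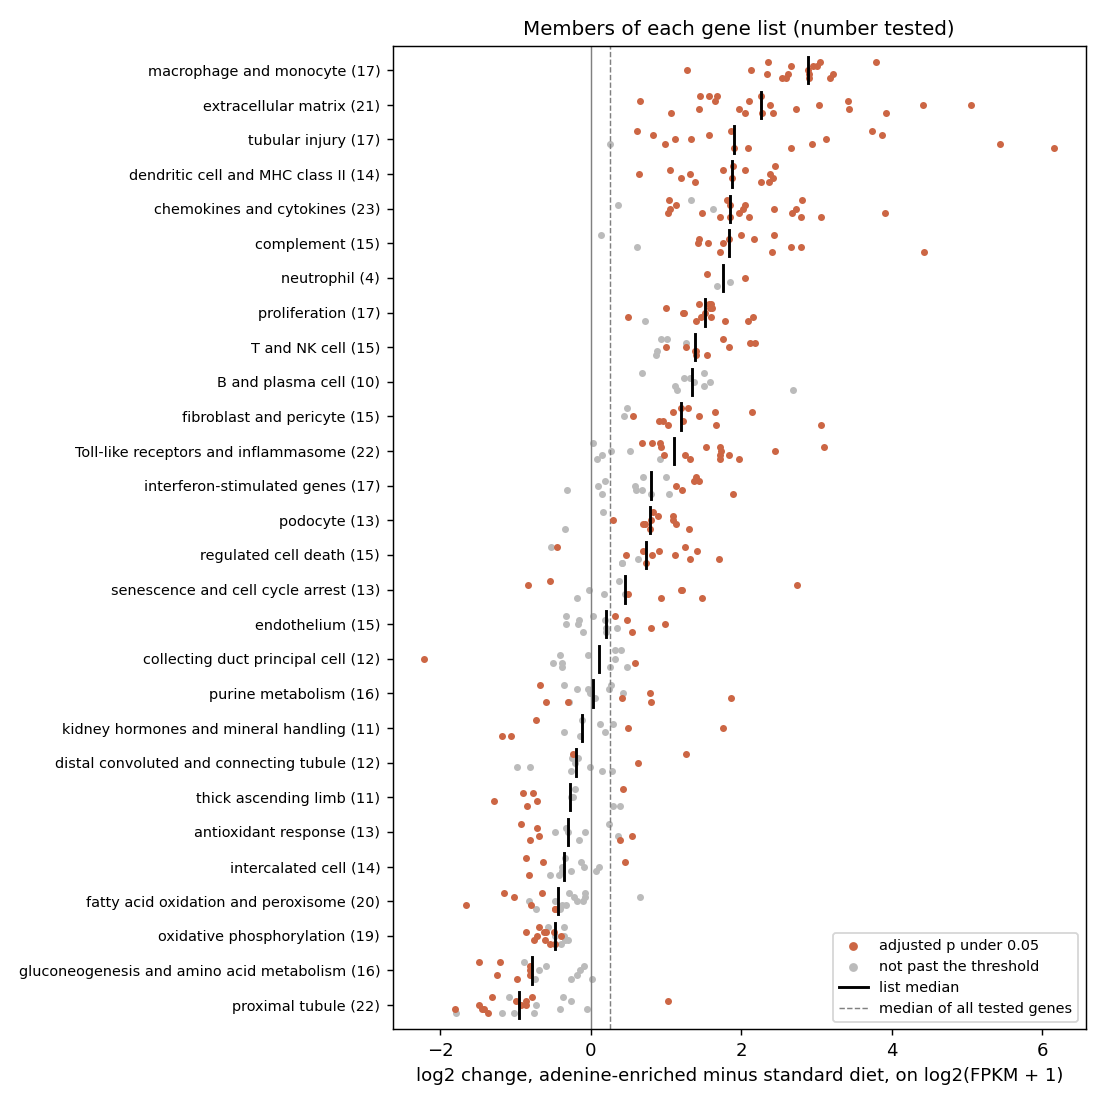
Each point is 1 gene of a list fixed before the data were examined, placed by its log2 change on log2(FPKM + 1) (x axis, adenine-enriched minus standard diet) and coloured where the limma adjusted p is under 0.05. Lists (y axis, with the number of tested members) are ordered by their median, the black tick, from -0.96 for proximal tubule genes to 2.89 for macrophage and monocyte genes, and the dashed line marks the median of all tested genes, 0.25.

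On the log2(FPKM + 1) scale, the largest rise among changed genes that reach 5 FPKM and whose groups do not overlap belonged to Havcr1, the kidney injury receptor also known as Kim1 (chromosome 11, 46735080 to 46779578, GRCm38), which went from 1.41 ± 0.0476 to 181 ± 81.2 FPKM, a 129-fold difference of means (limma adjusted p = 0.000798). Lcn2, a lipocalin released by injured tubules, rose from 6.07 ± 1.67 to 340.3 ± 175 FPKM (limma adjusted p = 0.00324), and Spp1, which encodes osteopontin, rose 14.9-fold to 6731 ± 2031 FPKM. Timp1, an inhibitor of matrix proteases, rose from 0.453 ± 0.176 to 49.2 ± 16.8 FPKM, and Mmp7, a matrix protease made by epithelia, rose from 0.154 ± 0.153 to 34.4 ± 17 FPKM (limma adjusted p = 0.00152 and 0.00296). The other 4 of the 8 largest rises were immunoglobulin V segments. Ighv5-16 was 33.9 to 82.8 FPKM in the adenine libraries against at most 1.18 on the standard diet, and Igkv1-88 was listed at 0 in all 3 standard libraries and at 40.2, 20.2 and 11.1 FPKM in adenine 1 to 3. Ighv1-42 and Ighv1-55 were highest in adenine 1, at 201 and 875 FPKM, against 18.8 and 40.9 in adenine 2 and 43.2 and 46.3 in adenine 3. On the standard diet both were highest in standard 1, at 2.77 and 17.6 FPKM. V segments resemble one another closely, so their reads can be shared between them and their single values are uncertain. Leaving out 1 library ended the call of Ighv1-55 (0.108 without standard 2, 0.115 without standard 3, 0.0514 without adenine 1, 0.0594 without adenine 2), as limma adjusted p. Calls ended with quantile normalization for Ighv1-55 (0.0547), with no filter for Ighv1-55 (0.0664) (limma adjusted p). Calls also ended with a robust variance prior for Ighv1-55 (0.0928).

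Dnase1, a secreted nuclease of the tubule (chromosome 16, 4036942 to 4040024), fell from 489 ± 64.2 to 50.9 ± 22 FPKM, a 9.62-fold difference (limma adjusted p = 0.00329). Aqp4, a water channel of the collecting duct (chromosome 18, 15389394 to 15403684), fell from 49.3 ± 12.2 to 9.86 ± 2.71 FPKM. The cytochrome P450 genes Cyp2d12 and Cyp4a12a fell 10.8-fold and 5.52-fold, and the aldo-keto reductase Akr1c18 fell 9.53-fold (limma adjusted p = 0.00508, 0.0274 and 0.00762). The histone gene Hist1h2bg fell from 12.6 ± 9.03 to 1.04 ± 0.658 FPKM, and the uncharacterised transcript RP23-272H13.2 fell from 7.94 ± 4.41 to 0.72 ± 0.848 FPKM. Gm25117, annotated as a small nucleolar RNA of 144 bp (chromosome 10, 111481493 to 111481636), was listed at 2316, 1337 and 4190.1 FPKM in standard 1 to 3 and at 0 in adenine 1 to 3. An RNA shorter than the sequenced fragments has no reliable FPKM, so no fold is given for it. Single omissions of a library ended limma calls for Cyp4a12a (0.0828 without standard 1, 0.0795 without standard 2, 0.0538 without adenine 2), as limma adjusted p. Among other settings, calls ended with a robust variance prior for Cyp4a12a (0.0501) (limma adjusted p).

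**Figure D2:**
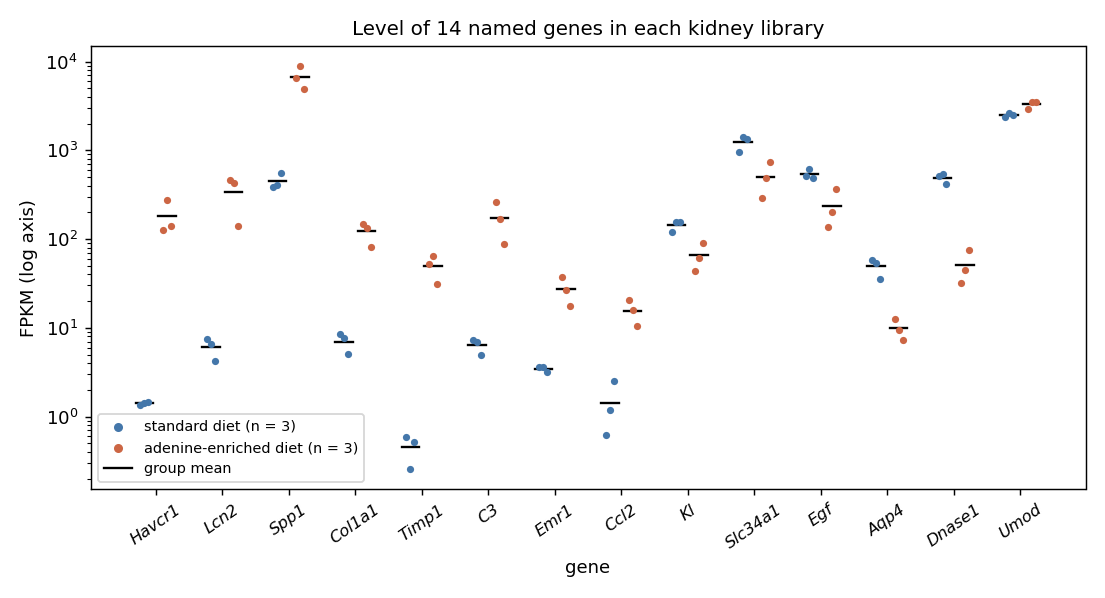
FPKM (y axis, log scale) of 14 named genes in each library, with a bar at each group mean. The 3 adenine libraries lie above all standard libraries for the genes from Havcr1 to Ccl2, by 128.5-fold in the mean for Havcr1, and below them from Kl to Dnase1. For Umod they also lie above, but by only 1.31-fold in the mean, a difference that limma did not call.

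Markers of injured tubules moved together. Of 17 measured genes of the tubular injury list, 16 rose, also 16 when adjusted over the list alone, with a median log2 change of 1.90 (1.76 and 15 genes after median-of-ratios scaling). Only Itgb6 did not pass, at a log2 change of 0.26. In contrast, 11 of 22 proximal tubule genes fell and 1 rose; adjusted over the list alone, 13 fell and 1 rose, and after median-of-ratios scaling 14 fell. The sodium phosphate transporters Slc34a3 and Slc34a1 fell 4.16-fold and 2.43-fold (limma adjusted p = 0.0104 and 0.0287), and the glucose transporter Slc5a2 fell from 105 ± 23.2 to 36.6 ± 7.5 FPKM. Lrp2, which encodes the endocytic receptor megalin, fell from 142 ± 29.2 to 79.6 ± 26.1 FPKM (limma adjusted p = 0.0497). The sulfate transporter Slc13a1 went the other way, from 129 ± 39.9 to 258 ± 41.9 FPKM (limma adjusted p = 0.0192, 0.0802 after median-of-ratios scaling). Compared with all other genes by camera, the injury list was higher (adjusted p = 7.69e-08) and the proximal tubule list lower (adjusted p = 1.56e-10). Both calls were lost with adjusted p = 0.503 with an estimated correlation, and fry did not call the proximal tubule list (adjusted p = 0.0851). The 11 falls became 6, 3 and 3 without standard 1, 2 and 3, and 7, 3 and 16 without adenine 1, 2 and 3. Calls were lost on leaving out 1 library for Slc34a1 (0.053 without standard 1, 0.0876 without standard 2, 0.0873 without standard 3, 0.0818 without adenine 2) and Lrp2 (0.0617 without standard 1, 0.125 without standard 2, 0.141 without standard 3, 0.0807 without adenine 1, 0.10 without adenine 2), as limma adjusted p. The same held for Slc13a1 (0.0525 without standard 1, 0.0629 without standard 2, 0.0681 without adenine 2). Calls were also lost with quantile normalization for Slc34a1 (0.0729) and Lrp2 (0.0762), with no filter for Slc34a1 (0.0548) and Lrp2 (0.0804) (limma adjusted p). The same was so with no variance trend for Lrp2 (0.057), and with rescaling without the 50 most abundant genes for Lrp2 (0.0517).

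In the thick ascending limb list, 5 of 11 genes fell (5 adjusted over the list alone, 6 after median-of-ratios scaling), led by Egf and Cldn10. Egf, the epidermal growth factor made by this segment, fell from 538 ± 66.2 to 237 ± 119.6 FPKM (limma adjusted p = 0.0301), and the claudin gene Cldn10 fell from 240.0 ± 7.32 to 131 ± 32.4 FPKM. Another claudin gene, Cldn16, rose from 7.98 ± 0.67 to 11.1 ± 0.501 FPKM (limma adjusted p = 0.0218), which did not hold after median-of-ratios scaling (adjusted p = 0.251). Umod, which encodes the main protein of normal urine, was 2506 ± 122 against 3293 ± 351 FPKM (limma adjusted p = 0.309), a log2 change of 0.39 that shrank to 0.09 after median-of-ratios scaling. Its call depended on how the spread of very abundant genes was estimated, since adjusted p = 0.044 in limma without a variance trend, and it ranged up to 0.856 over the other alternatives. By camera the list was lower than other genes (adjusted p = 0.000742, and adjusted p = 0.503 with an estimated correlation), which was lost with quantile normalization (0.104) and by fry (0.172). The 5 falls became 1, 1 and 2 without standard 1, 2 and 3, and 0 without adenine 2. Leaving out a library also ended the calls of Cldn16 (0.0683 without standard 2, 0.065 without standard 3, 0.0924 without adenine 2) and Egf (0.0766 without standard 1, 0.0895 without standard 2, 0.0731 without standard 3, 0.0916 without adenine 2), as limma adjusted p. This was also so for Cldn10 (0.0526 without adenine 2). Other settings ended calls, with quantile normalization for Cldn16 (0.905) and Egf (0.0556), with no filter for Egf (0.0531) (limma adjusted p). Calls also ended with block and median-of-ratios scaling together for Cldn16 (0.31).

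Among 12 distal convoluted and connecting tubule genes, the calcium channel Trpv5 rose from 3.5 ± 1.24 to 9.78 ± 3.22 FPKM and the magnesium channel Trpm6 rose from 2.21 ± 0.489 to 3.99 ± 0.889 FPKM, while Trpm7 fell from 38.9 ± 0.632 to 33 ± 0.73 FPKM (limma adjusted p = 0.0178, 0.0418 and 0.0438). Adjusted over the list alone, Trpv5 remained as the 1 rise and no gene fell, and Trpm6 and Trpm7 were not called with the replicate number as a block (adjusted p = 0.0614 and 0.0685), which gave 1 rise and 2 falls. After median-of-ratios scaling 1 distal gene rose and 2 fell. Aqp4 and Stmn1 were the changes among 12 principal cell genes, 1 down and 1 up, also when adjusted over the list alone; the rise of Stmn1, from 22 ± 2.07 to 34 ± 6.15 FPKM, ended after median-of-ratios scaling (adjusted p = 0.121), where none rose and 4 fell. Of 14 intercalated cell genes, Atp6v1g3, Slc4a1 and Atp6v1c2 fell and Kit rose. Adjusted over the list alone, 1 fell and none rose, and after median-of-ratios scaling 4 fell and none rose. Atp6v1g3, a subunit of the proton pump, fell from 26.6 ± 2.75 to 14.8 ± 2.01 FPKM (limma adjusted p = 0.00762), and the anion exchanger Slc4a1 fell from 57.4 ± 12.2 to 31.6 ± 8.83 FPKM (adjusted p = 0.039, 0.0503 with the block, which gave 1 fall in the list). Kit was 5.06 ± 0.571 against 7.33 ± 1.02 FPKM (adjusted p = 0.0445, 0.185 after median-of-ratios scaling). Camera placed the intercalated and distal lists below other genes (adjusted p = 0.000438 and 0.0378), each with adjusted p = 0.503 with an estimated correlation, and the principal cell list was not called (adjusted p = 0.164). With 1 library left out, the intercalated falls became 1, 1 and 2 without standard 1, 2 and 3, 1 and 1 without adenine 1 and 2, and 7 without adenine 3. The rise of Kit was absent without each library except adenine 3. In the distal list nothing changed without standard 1, standard 2 or adenine 2, 1 gene rose and none fell without standard 3 or adenine 1, and 2 fell without adenine 3. Its camera call was lost after median-of-ratios scaling and with quantile normalization (0.121 and 0.536) and without standard 2, standard 3 and adenine 1 (0.070, 0.0953 and 0.17), and the principal cell list was called without standard 3 (0.0139), where 4 of its genes fell. Fry called neither the intercalated nor the distal list (adjusted p = 0.267 and 0.815). Some sets of 5 libraries gave no call for Trpv5 (0.0512 without standard 1, 0.0533 without standard 2, 0.0549 without adenine 2) and Trpm6 (0.117 without standard 1, 0.0597 without standard 2, 0.102 without standard 3, 0.102 without adenine 1, 0.116 without adenine 2), as limma adjusted p. Further calls ended for Trpm7 (0.116 without standard 1, 0.109 without standard 2, 0.096 without standard 3, 0.0882 without adenine 1, 0.13 without adenine 2, 0.0586 without adenine 3) and Stmn1 (0.0538 without standard 1, 0.0772 without standard 2, 0.0642 without standard 3, 0.0754 without adenine 2). Calls also ended for Kit (0.102 without standard 1, 0.0737 without standard 2, 0.12 without standard 3, 0.115 without adenine 1, 0.119 without adenine 2) and Slc4a1 (0.106 without standard 1, 0.113 without standard 2, 0.0638 without adenine 1, 0.0675 without adenine 2). Of the other settings, calls did not hold with quantile normalization for Trpv5 (0.0919), Trpm6 (0.592), Stmn1 (0.0759) and Kit (0.924), with no filter for Trpm6 (0.0752), Kit (0.0719) and Slc4a1 (0.0644) (limma adjusted p). This also held with a mean of at least 5 FPKM for Kit (0.0578), and with no variance trend for Trpm7 (0.0798). The same was so with a robust variance prior for Trpm7 (0.0532), and with rescaling without the 50 most abundant genes for Kit (0.0617). Calls also ended with block and median-of-ratios scaling together for Trpm6 (0.141), Stmn1 (0.118) and Kit (0.195), and with median-of-ratios scaling for Trpm6 (0.0986).

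In 3 lists of energy metabolism some genes fell and none rose. In oxidative phosphorylation 11 of 19 genes fell (14 adjusted over the list alone, 16 after median-of-ratios scaling), with a median log2 change of -0.48 (-0.78 after scaling). Cytochrome c (Cycs) fell from 135 ± 9.91 to 75.5 ± 23.9 FPKM and the succinate dehydrogenase subunit Sdhb from 201 ± 10.8 to 120.2 ± 25.7 FPKM (limma adjusted p = 0.0232 and 0.0154). In fatty acid oxidation and peroxisome 7 of 20 fell (9 adjusted over the list alone, 12 after scaling), led by Acsm2, from 1577 ± 147 to 571 ± 335 FPKM, and the medium-chain dehydrogenase Acadm, from 607 ± 39.3 to 281 ± 93.1 FPKM (limma adjusted p = 0.0336 and 0.015). In gluconeogenesis and amino acid metabolism 7 of 16 fell (8 adjusted over the list alone, 9 after scaling), among them Gatm, the first enzyme of creatine synthesis, from 201 ± 74.3 to 80.3 ± 6.53 FPKM. By camera the 3 lists were lower than other genes (adjusted p = 1.61e-11, 5.83e-09 and 5.56e-08), each with adjusted p = 0.503 with an estimated correlation, and fry called none of them (adjusted p = 0.0531, 0.0888 and 0.0791). In oxidative phosphorylation the 11 falls became 2 without each of standard 1, 2 and 3, and 7, 0 and 18 without adenine 1, 2 and 3. In fatty acid oxidation the 7 became 4, 1 and 0 without standard 1, 2 and 3 and 4, 0 and 12 without adenine 1, 2 and 3, and in gluconeogenesis 4, 1 and 2, and 4, 1 and 11. Omission of 1 library removed the call of Acsm2 (0.0772 without standard 1, 0.0903 without standard 2, 0.0954 without standard 3, 0.0845 without adenine 2) and Acadm (0.0508 without standard 1, 0.0528 without standard 3, 0.0572 without adenine 2), as limma adjusted p. Calls also ended for Cycs (0.0624 without standard 1, 0.0614 without standard 2, 0.0761 without standard 3, 0.0798 without adenine 2) and Sdhb (0.0535 without standard 1, 0.060 without adenine 2). The same held for Gatm (0.0545 without standard 2, 0.0557 without adenine 2). Further losses of calls came with quantile normalization for Acsm2 (0.0755), with no filter for Acsm2 (0.0629) (limma adjusted p).

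Of 13 antioxidant genes, 4 fell and 2 rose, also when adjusted over the list alone. The superoxide dismutases Sod1 and Sod2 fell 1.87-fold and 1.74-fold (limma adjusted p = 0.0169 and 0.0167), as did Cat and Gstm1, at log2 changes of -0.71 and -0.69. Glutathione reductase (Gsr) rose from 59.1 ± 1.97 to 87.5 ± 13.6 FPKM and Srxn1 from 25.3 ± 3.12 to 33.4 ± 1.52 FPKM, and neither was called after median-of-ratios scaling (limma adjusted p = 0.274 and 0.566). Camera placed the list below other genes (adjusted p = 0.0118, and adjusted p = 0.535 with an estimated correlation), with a median log2 change of -0.30 (-0.60 after scaling). The 4 falls became 1, 0 and 0 without standard 1, 2 and 3, and 2 and 0 without adenine 1 and 2, and the camera call was lost without standard 3 and adenine 1 (0.115 and 0.0782), with quantile normalization (0.641), with no filter (0.0701) and by fry (0.54). After median-of-ratios scaling 4 fell and none rose. Leaving out 1 library ended the call of Gsr (0.0543 without standard 1, 0.065 without standard 2, 0.0656 without standard 3, 0.0768 without adenine 2) and Srxn1 (0.077 without standard 1, 0.0705 without standard 2, 0.0513 without standard 3, 0.0665 without adenine 1, 0.119 without adenine 2), as limma adjusted p. The same held for Sod1 (0.0582 without standard 1, 0.0536 without standard 2, 0.052 without standard 3, 0.0677 without adenine 2) and Sod2 (0.0546 without standard 2, 0.0564 without standard 3, 0.0596 without adenine 2). Calls ended with quantile normalization for Srxn1 (0.199), with rescaling without the 50 most abundant genes for Srxn1 (0.0637) (limma adjusted p). Calls also ended with block and median-of-ratios scaling together for Gsr (0.253) and Srxn1 (0.412).

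Of 13 glomerular podocyte genes measured 11 rose, and 11 also when adjusted over the list alone, where a further gene, Clic5, fell. The filament gene Nes rose from 5.32 ± 0.471 to 13 ± 2.5 FPKM (limma adjusted p = 0.00598). After median-of-ratios scaling 8 rose and Clic5 fell, and the list median moved from 0.79 to 0.52. By camera the list was higher than other genes (adjusted p = 0.00899, and adjusted p = 0.503 with an estimated correlation). Of 15 endothelial genes 5 rose, Plat, Cldn5, Eng, Tie1 and Egfl7, and 5 when adjusted over the list alone, at a list median of 0.20. Plat, the tissue plasminogen activator, rose from 47.5 ± 13.9 to 93.5 ± 19.1 FPKM and the claudin gene Cldn5 from 7.15 ± 0.208 to 13.3 ± 2.13 FPKM (limma adjusted p = 0.0239 and 0.0080). After median-of-ratios scaling 2 endothelial genes rose and 4 fell, and the list median was -0.10. Camera made no call, before scaling (adjusted p = 0.773, with its direction down although the median was above 0) or after it (adjusted p = 0.319). The podocyte count was 7 without standard 2 and 6 without standard 3. The endothelial count became 3, 3 and 2 without standard 1, 2 and 3, and 2 and 1 without adenine 1 and 2. Single omissions of a library ended limma calls for Plat (0.0685 without standard 1, 0.0635 without standard 3, 0.0611 without adenine 1, 0.0766 without adenine 2), as limma adjusted p.

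All 21 measured extracellular matrix genes rose, also adjusted over the list alone, and 20 after median-of-ratios scaling. The fibrillar collagen genes Col3a1 and Col1a1 rose 23.6-fold and 17.4-fold, Col3a1 from 19.1 ± 1.52 to 451 ± 164 FPKM and Col1a1 from 7.01 ± 1.77 to 122 ± 35.1 FPKM (limma adjusted p = 0.00295 and 0.00295). The median log2 change of the list was 2.26 (1.99 after scaling). Of 15 fibroblast and pericyte genes, 13 rose (14 adjusted over the list alone, 11 after scaling), and Fap and Myl9 did not pass, at log2 changes of 0.44 and 0.48. Thy1, a surface protein of fibroblasts and T cells, rose from 1.4 ± 0.423 to 19.8 ± 8.49 FPKM, vimentin (Vim) from 27 ± 4.83 to 127 ± 49.8 FPKM, and Acta2, the smooth muscle actin of myofibroblasts and vessel walls, from 37.3 ± 4.25 to 78.7 ± 22.2 FPKM (limma adjusted p = 0.00383, 0.00525 and 0.0123). Both lists were higher than other genes by camera (adjusted p = 1.08e-09 and 0.000132), and each had adjusted p = 0.503 with an estimated correlation.

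The macrophage list had the highest median of all 37 lists. All 17 macrophage and monocyte genes rose, adjusted over the list alone and after median-of-ratios scaling as well, with a median log2 change of 2.89 (2.61 after scaling). Emr1, the gene of the macrophage surface antigen now called Adgre1, rose from 3.46 ± 0.23 to 27.1 ± 9.99 FPKM (limma adjusted p = 0.00361), and Lyz2, Gpnmb and the rest lay 1.28 to 3.78 log2 units up. Lysozyme (Lyz2) reached 738 ± 379.6 FPKM from 49.3 ± 10.2, and Gpnmb rose from 0.182 ± 0.0373 to 10.7 ± 5.03 FPKM. All 14 dendritic cell and MHC class II genes rose, also adjusted over the list alone and after scaling, among them Itgax, from 1.24 ± 0.173 to 11.5 ± 3.78 FPKM, and H2-Ab1, from 79.9 ± 12.8 to 452 ± 189 FPKM (limma adjusted p = 0.00332 and 0.00486). Of 4 measured neutrophil genes, Csf3r and Mmp9 rose (all 4 adjusted over the list alone, 2 after scaling), Csf3r from 0.44 ± 0.0998 to 5.03 ± 1.32 FPKM and Mmp9 from 0.27 ± 0.103 to 2.76 ± 0.866 FPKM. The others, S100a8 and S100a9, were above the standard mean in all adenine libraries and missed the threshold (limma adjusted p = 0.0591 and 0.0554), with a value of 6.9 FPKM for S100a8 in standard 3. By camera the macrophage and the dendritic cell list were higher (adjusted p = 5.83e-09 and 1.28e-05, each with adjusted p = 0.503 with an estimated correlation). Without standard 3 or adenine 3, 4 neutrophil genes passed.

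Lymphocyte genes were uneven between the adenine libraries. Of 15 T and NK cell genes, 10 rose (14 adjusted over the list alone, 7 after median-of-ratios scaling). Cd4 rose from 0.94 ± 0.465 to 8.32 ± 4.75 FPKM, Lck from 1.23 ± 0.53 to 10.2 ± 8.04 FPKM and Cd3e from 0.485 ± 0.148 to 3.51 ± 3.08 FPKM (limma adjusted p = 0.00888, 0.0196 and 0.0439), and Cd3e was not called after scaling (adjusted p = 0.0545). Cd3e stood at 7.07 FPKM in adenine 1 against 1.8 and 1.65 in adenine 2 and 3. None of 10 B and plasma cell genes passed limma's test, over all genes, adjusted over the list alone, or after scaling, and 2 had an unadjusted p under 0.05. The lowest adjusted p was that of Igj, the joining chain of secreted immunoglobulin, at 436, 52.2 and 81.1 FPKM in adenine 1 to 3 against 25.3 ± 25.5 (adjusted p = 0.0653). With the replicate number as a block Igj was called (adjusted p = 0.00758), the 1 gene of that list, and 1 gene passed without adenine 3. The median of the B and plasma cell list was 3.18 log2 units above the standard mean in adenine 1 and 0.35 and 0.36 in adenine 2 and 3. Camera placed the T and NK cell list above other genes (adjusted p = 0.0105, and adjusted p = 0.606 with an estimated correlation) and not the B and plasma cell list (adjusted p = 0.476). Fry did not call the T and NK cell list (adjusted p = 0.0767), and camera called the B and plasma cell list upward with the block and median-of-ratios scaling together (adjusted p = 0.00858). Without adenine 1, 9 T and NK cell genes rose; the count became 2, 2 and 3 without standard 1, 2 and 3, and 2 without adenine 2. Calls were lost on leaving out 1 library for Cd3e (0.0915 without standard 1, 0.114 without standard 2, 0.11 without standard 3, 0.0654 without adenine 2) and Lck (0.0627 without standard 1, 0.0638 without standard 2, 0.0543 without adenine 2), as limma adjusted p. Among other settings, calls ended with quantile normalization for Cd3e (0.0873), with no filter for Cd3e (0.0728) (limma adjusted p). Calls were gained with block and median-of-ratios scaling together for Igj (0.0104), with protein-coding genes only for Igj (0.0441) (limma adjusted p).

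**Figure D3:**
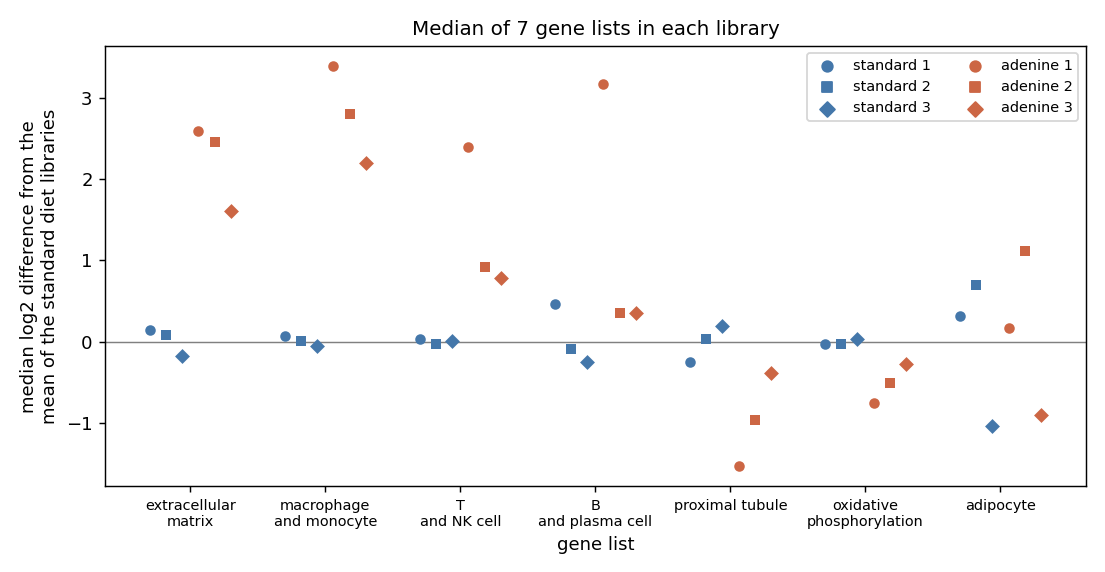
Median log2 difference (y axis) of the tested members of 7 gene lists (x axis) in each library from the mean of the 3 standard diet libraries. The extracellular matrix, macrophage, proximal tubule and oxidative phosphorylation medians part the 2 diets in all libraries, while the B and plasma cell median is 3.18 in adenine 1 and at most 0.47 elsewhere, and the adipocyte median is lowest in replicate 3 of both diets.

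Of 23 chemokine and cytokine genes, 20 rose (21 adjusted over the list alone, 19 after median-of-ratios scaling), and Ccl28, Cxcl9 and Cxcl13 did not pass, at log2 changes of 0.37, 1.62 and 1.33. The monocyte attractant Ccl2 rose from 1.44 ± 0.978 to 15.6 ± 4.95 FPKM, Ccl8 from 3.17 ± 1.75 to 44 ± 42.5 FPKM, the neutrophil attractant Cxcl5 from 0.0307 ± 0.0271 to 15.6 ± 6.82 FPKM, and the cytokine Il1b from 1.83 ± 0.807 to 10.6 ± 3.57 FPKM (limma adjusted p = 0.00489, 0.0186, 0.00324 and 0.00722). Among 22 Toll-like receptor and inflammasome genes 16 rose (16 adjusted over the list alone, 14 after scaling). Clec7a, the dectin receptor of fungal glucans, rose from 2.94 ± 1.05 to 34.3 ± 16.6 FPKM, Casp4 from 2.3 ± 0.255 to 17.8 ± 6.45 FPKM and Tlr2 from 2.01 ± 0.497 to 9.94 ± 3.32 FPKM. Nlrp3, the inflammasome sensor, rose from 0.424 ± 0.233 to 1.5 ± 0.446 FPKM (adjusted p = 0.0254, 0.0524 with the replicate number as a block). In the complement list 13 of 15 rose (14 adjusted over the list alone, 13 after scaling), with C3 from 6.39 ± 1.26 to 173 ± 87.4 FPKM and Cfi from 1.42 ± 0.39 to 15.8 ± 3.58 FPKM, and Cfb and Masp1 did not pass, at 0.13 and 0.62. These 3 lists were higher than other genes by camera (adjusted p = 1.60e-06, 0.000742 and 7.80e-06), with adjusted p = 0.503, 0.524 and 0.503 with an estimated correlation. The 16 Toll-like receptor and inflammasome genes became 10 without adenine 2. Leaving out a library also ended the calls of Nlrp3 (0.0767 without standard 1, 0.0705 without standard 2, 0.0608 without adenine 1, 0.0874 without adenine 2) and Ccl8 (0.0582 without standard 2, 0.0642 without standard 3, 0.0549 without adenine 2), as limma adjusted p. Calls were also lost with quantile normalization for Nlrp3 (0.171), with block and median-of-ratios scaling together for Nlrp3 (0.0816) (limma adjusted p).

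Of 17 interferon-stimulated genes measured 6 rose, and 6 adjusted over the list alone (5 up and 1 down after median-of-ratios scaling), and camera did not call the list (adjusted p = 0.0973), although it did after median-of-ratios scaling and with quantile normalization (0.0316 and 0.0142) and without adenine 3 (0.00094). The proteasome subunit Psmb8 rose from 9.02 ± 1.8 to 38.5 ± 19.6 FPKM and the guanylate-binding protein Gbp2 from 8.28 ± 2.23 to 26.1 ± 14 FPKM (limma adjusted p = 0.0101 and 0.0312); Gbp2 was not called after scaling (adjusted p = 0.0546). The median of the list lay 1.27, 1.01 and 0.20 log2 units above the standard mean in adenine 1, 2 and 3. Without adenine 3, 15 of the 17 rose; without standard 1, 2 and 3 the count was 3, 2 and 2, and without adenine 2 it was 2. Some sets of 5 libraries gave no call for Gbp2 (0.0836 without standard 1, 0.0925 without standard 2, 0.0575 without standard 3, 0.0863 without adenine 2), as limma adjusted p. Other settings ended calls, with quantile normalization for Gbp2 (0.0689), with no filter for Gbp2 (0.0543) (limma adjusted p). Calls also ended with block and median-of-ratios scaling together for Gbp2 (0.0807).

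Of 17 proliferation genes 16 rose (17 adjusted over the list alone, 15 after median-of-ratios scaling), with Bub1 not passing over all genes at 0.72. Top2a rose from 1.34 ± 0.489 to 10 ± 5.19 FPKM and the cyclin-dependent kinase Cdk1 from 2.72 ± 1.41 to 15.9 ± 8.75 FPKM (limma adjusted p = 0.00762 and 0.0231). The arrest gene Cdkn1a, which encodes p21, rose from 5.69 ± 1.22 to 18.1 ± 6.32 FPKM (limma adjusted p = 0.011). Of 13 senescence and arrest genes 6 rose and 2 fell, also adjusted over the list alone (5 and 3 after scaling). Igfbp3 fell from 113 ± 9.72 to 64.3 ± 16.6 FPKM and Glb1 from 69.9 ± 5.56 to 48.5 ± 11.1 FPKM, Glb1 with adjusted p = 0.0451 and 0.0653 with the block. Of 15 regulated cell death genes 10 rose and Bid fell (12 and 2 adjusted over the list alone, 6 and 2 after scaling). Tnfrsf12a, the receptor of the TWEAK cytokine, rose from 11.1 ± 2.06 to 38.1 ± 4.67 FPKM and Bbc3, which encodes the death effector PUMA, from 1.36 ± 0.611 to 5.23 ± 1.4 FPKM, while Bid was 24.9 ± 4.35 against 17.7 ± 1.33 FPKM (adjusted p = 0.0419, 0.0517 with the block). Immediate early genes, included as a check on handling and stress, rose in 11 of 12 cases (11 adjusted over the list alone, 11 up and 1 down after scaling), with Dusp1 at -0.21. Egr2 rose from 0.353 ± 0.115 to 6.33 ± 2.75 FPKM and Junb from 9.83 ± 1.46 to 52.7 ± 14.7 FPKM. Camera placed the proliferation, cell death and immediate early lists above other genes (adjusted p = 8.92e-05, 0.0352 and 0.000742, each with adjusted p = 0.503 with an estimated correlation), and not the senescence list (adjusted p = 0.476), which fry called upward (adjusted p = 0.00773). Without adenine 2 the proliferation and cell death counts were 10 and 4; proliferation was 11 and 11 without standard 1 and 2, and cell death 6 and 5. The cell death list was not called by camera without standard 2 (0.0664) or with a mean of at least 5 FPKM (0.141). No senescence gene fell without adenine 2 or any 1 of standard 1 to 3, and 1 fell without adenine 1. Omission of 1 library removed the call of Igfbp3 (0.0603 without standard 1, 0.0579 without standard 2, 0.0743 without standard 3, 0.0504 without adenine 2) and Glb1 (0.11 without standard 1, 0.125 without standard 2, 0.0816 without standard 3, 0.0966 without adenine 1, 0.128 without adenine 2), as limma adjusted p. This was also so for Cdk1 (0.068 without standard 1, 0.0594 without standard 2, 0.0553 without adenine 1, 0.0771 without adenine 2) and Bid (0.0515 without standard 1, 0.0838 without standard 2, 0.0869 without standard 3, 0.0627 without adenine 1, 0.134 without adenine 2, 0.0649 without adenine 3). Of the other settings, calls did not hold with quantile normalization for Glb1 (0.0508) and Cdk1 (0.0501), with no filter for Glb1 (0.0689) and Bid (0.0605) (limma adjusted p). This also held with no variance trend for Glb1 (0.0562) and Bid (0.0528), and with rescaling without the 50 most abundant genes for Glb1 (0.0506). The same was so with block and median-of-ratios scaling together for Cdk1 (0.0652).

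Some genes of purine metabolism, the pathway that handles adenine, rose and others fell. Of 16 measured genes 4 rose, Gda, Xdh, Ampd2 and Gart, and 3 fell, Abcg2, Adk and Paics, also adjusted over the list alone (3 and 4 after median-of-ratios scaling). Over all 15431 tested genes 4581 rose and 1056 fell, so the list had a lower share of rises and a higher share of falls. Guanine deaminase (Gda) rose from 1.49 ± 0.22 to 8.42 ± 3.59 FPKM, and xanthine dehydrogenase (Xdh), which oxidises adenine as well as xanthine, rose from 7.12 ± 0.888 to 13.2 ± 2.69 FPKM (limma adjusted p = 0.00683 and 0.0163). The urate exporter Abcg2 fell from 224 ± 36.8 to 141 ± 33.3 FPKM and adenosine kinase (Adk) from 146 ± 9.0 to 97.9 ± 22.3 FPKM (limma adjusted p = 0.0412 and 0.034). Aprt, which salvages adenine, was not analysed here. The list was not called by camera (adjusted p = 0.311), whose direction was down while the median log2 change was 0.03. The 3 falls were absent without adenine 1, adenine 2 or any 1 of standard 1 to 3, and 2 genes rose without standard 1 or adenine 2. Leaving out 1 library ended the call of Xdh (0.0558 without standard 1, 0.0554 without standard 2, 0.0631 without adenine 2) and Abcg2 (0.0524 without standard 1, 0.111 without standard 2, 0.121 without standard 3, 0.0926 without adenine 1, 0.116 without adenine 2), as limma adjusted p. Further calls ended for Adk (0.0776 without standard 1, 0.0824 without standard 2, 0.102 without standard 3, 0.0661 without adenine 1, 0.104 without adenine 2). Further losses of calls came with quantile normalization for Xdh (0.0839), Abcg2 (0.0883) and Adk (0.0617), with no filter for Abcg2 (0.0661) and Adk (0.0536) (limma adjusted p). The same was so with block and median-of-ratios scaling together for Xdh (0.0872).

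In the list of kidney hormones and mineral handling, 2 of 11 genes rose, Cyp27b1 and Fgfr1, and 3 fell, Kl, Ace and Vdr, also adjusted over the list alone (1 and 4 after median-of-ratios scaling). Klotho (Kl), the co-receptor of a phosphate-regulating hormone, fell from 144 ± 20.3 to 65.3 ± 23.4 FPKM (limma adjusted p = 0.0174), and angiotensin-converting enzyme (Ace) fell from 84.4 ± 7.73 to 41.3 ± 13.8 FPKM (limma adjusted p = 0.0191). Cyp27b1, which makes active vitamin D, rose from 0.227 ± 0.196 to 3.22 ± 1.24 FPKM (limma adjusted p = 0.00628), and the vitamin D receptor gene Vdr fell, at a log2 change of -0.73. Fgfr1 rose from 23.8 ± 3.12 to 33.8 ± 3.0 FPKM, and not after median-of-ratios scaling (adjusted p = 0.219). Renin (Ren1) was 44.7 ± 2.66 against 52.5 ± 14.5 FPKM (limma adjusted p = 0.488), and its log2 change went from 0.19 to -0.10 with that scaling. Epo was below the expression filter, at 0, 0 and 0.326 FPKM in standard 1 to 3 and 0.083, 0.061 and 0.216 in adenine 1 to 3. Camera placed the list below other genes (adjusted p = 0.040, and adjusted p = 0.503 with an estimated correlation), which was lost after median-of-ratios scaling and with quantile normalization (0.119 and 0.477), with no filter (0.0973), by fry (0.815), with the block and median-of-ratios scaling together (0.090), and without adenine 1, adenine 2 or standard 3 (0.145, 0.0591 and 0.0714). The 3 falls became 1, 0 and 1 without standard 1, 2 and 3 and 0 without adenine 2. Single omissions of a library ended limma calls for Kl (0.0584 without standard 2, 0.0603 without standard 3, 0.0593 without adenine 2) and Fgfr1 (0.0621 without standard 1, 0.0573 without standard 3, 0.0666 without adenine 1, 0.0856 without adenine 2), as limma adjusted p. Calls also ended for Ace (0.060 without standard 1, 0.063 without standard 2, 0.0556 without adenine 2). Ren1 (0.0298 without adenine 1) passed with that library left out (limma adjusted p). Calls ended with quantile normalization for Fgfr1 (0.084), with block and median-of-ratios scaling together for Fgfr1 (0.226) (limma adjusted p).

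Markers of tissue that can come with a whole kidney were examined as checks. None of the 6 red blood cell, 9 adipocyte, 9 urothelial or 3 skeletal muscle genes passed limma's test, over all genes or adjusted over the list alone, and 0, 0, 3 and 1 of them had an unadjusted p under 0.05. The red cell list was led by Hbb-bs at 18.5 ± 16.6 against 32.1 ± 29.8 FPKM, and the adipocyte list by Fabp4 at 155 ± 35.5 against 107 ± 39.2 FPKM (limma adjusted p = 0.469 and 0.155). Adjusted p was 0.062 for Trp63 of the urothelium and 0.083 for Pvalb of fast muscle, which is also a gene of the distal convoluted tubule and was called with the block (0.0369). The block also called 2 urothelial genes. Of 2 adrenal genes Akr1b7 rose, also adjusted over the list alone, from 2.46 ± 0.215 to 3.56 ± 0.314 FPKM (adjusted p = 0.0493, 0.0601 with the block), and it was not called after median-of-ratios scaling (adjusted p = 0.268). Of 6 lymphatic vessel genes Pdpn, Ccl21a and Flt4 rose, also adjusted over the list alone (2 after median-of-ratios scaling, but 1 up and 2 down with quantile normalization), and fry called the list upward (adjusted p = 0.0197); Pdpn, also a podocyte gene, rose from 3.31 ± 0.681 to 17.4 ± 5.46 FPKM and Ccl21a from 3.11 ± 0.507 to 6.21 ± 0.884 FPKM. None of 4 sex-linked genes passed (0 at an unadjusted p under 0.05), led by Kdm5d at 7.77 ± 1.44 against 10.1 ± 1.05 FPKM (limma adjusted p = 0.105). Reference genes were not steady: of 12, Actb, Gusb and Rplp0 rose and 1 fell, and 3 rose and 3 fell when adjusted over the list alone. Actb rose from 345 ± 43.8 to 726 ± 177 FPKM and Gusb from 22.1 ± 4.08 to 33.2 ± 5.34 FPKM. After median-of-ratios scaling 1 rose and 3 fell. Camera called none of the red cell, adipocyte, urothelial, lymphatic and reference lists (adjusted p = 0.661, 0.0945, 0.808, 0.665 and 0.417), and lists with under 5 tested genes were not tested by it. The adipocyte list was called lower without standard 3 and adenine 2 (0.0132 and 0.00443). Of the reference genes 1, 1, 0 and 0 rose without standard 1, 2 and 3 and adenine 2, and 3 fell without adenine 3. Calls were lost on leaving out 1 library for Akr1b7 (0.0881 without standard 1, 0.14 without standard 2, 0.108 without standard 3, 0.122 without adenine 1, 0.141 without adenine 2) and Actb (0.0524 without standard 3, 0.0508 without adenine 2), as limma adjusted p. The same held for Gusb (0.0508 without standard 1, 0.0865 without standard 2, 0.0981 without standard 3, 0.0967 without adenine 1, 0.0864 without adenine 2). Pvalb (0.00861 without adenine 3) passed with that library left out (limma adjusted p). Among other settings, calls ended with quantile normalization for Akr1b7 (0.428, at a log2 change of -0.125), Ccl21a (0.247) and Gusb (0.10), with no filter for Akr1b7 (0.0916) and Gusb (0.0618) (limma adjusted p). This also held with a robust variance prior for Akr1b7 (0.055), and with rescaling without the 50 most abundant genes for Akr1b7 (0.0681) and Gusb (0.053). The same was so with block and median-of-ratios scaling together for Akr1b7 (0.296) and Gusb (0.0717), and with median-of-ratios scaling for Gusb (0.154). Calls were gained with no variance trend for Trp63 (0.0438), with block and median-of-ratios scaling together for Pvalb (0.0252) (limma adjusted p).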

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

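The settings without genes under 300 bp, with protein-coding genes only, and with the block and median-of-ratios scaling together were chosen after seeing the data. The number of changed genes stayed within 1.5 times of 5637 under every setting of pseudocount, filter, scaling, variance prior and block, from 4120 (mean of at least 5 FPKM, 10484 genes tested) to 5957 (replicate block), and was 1478 at adjusted p under 0.01. A similar count did not mean the same genes. Of the 5637, 3654 were also called with median-of-ratios scaling and 3014 with quantile normalization, all with the same sign. The count was 2920, 2949, 2796, 3617 and 2124 without standard 1, 2 and 3 and adenine 1 and 2, and 7047 without adenine 3. Fewer samples tend to lower the count, and the cause of the rise was not tested. Of the adenine libraries, adenine 3 was nearest to the standard diet. Its log2 values correlated at 0.926 to 0.932 with the standard libraries, against 0.901 to 0.913 for adenine 2 and 0.826 to 0.86 for adenine 1. Genes changed at least 2-fold numbered 1005 of those with a mean of 5 FPKM or more and 477 with limma's treat test against 1.5-fold, and otherwise 1160 (quantile) to 2449 (pseudocount 0.1). Camera called 22 of 33 lists, fry 14, and none was called with an estimated correlation, where the lowest adjusted p was 0.503; fry called none of the 9 lists that camera placed lower, nor the T and NK cell list, and the other settings gave 19 to 23. The replicate block called 5957 genes, 5150 of them shared with the unblocked fit and all with the same sign; apart from the genes and lists named with it in the report, it changed no call of a named gene or list test, and it gave 1 rising distal gene, 1 falling intercalated gene and 1 rising B cell gene.

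Counts within lists moved with the filter, the scaling and the omission of libraries, and unless said the cause was not tested. With no filter, 4 proximal tubule, 1 intercalated, 4 fatty acid oxidation and 2 antioxidant genes fell and 1 distal and 4 T and NK cell genes rose. With a mean of at least 5 FPKM, which removes members, 1 distal, 1 T and NK cell, 8 dendritic cell, 0 neutrophil, 8 Toll-like receptor and inflammasome and 5 proliferation genes rose. Median-of-ratios scaling gave 1 distal, 0 principal cell, 2 endothelial and 6 cell death genes rising and 12 fatty acid oxidation genes falling. Quantile normalization gave 7 proximal tubule, 3 thick ascending limb, 5 oxidative phosphorylation and 2 antioxidant genes falling and 0 distal, 0 principal cell, 5 podocyte, 3 endothelial, 3 T and NK cell, 2 purine and 4 cell death genes rising. It also gave falls in lists with fewer or none before: 3 principal cell, 4 intercalated, 1 podocyte, 3 endothelial, 1 interferon-stimulated and 2 lymphatic vessel genes. For lymphatic vessel, 1 rose with a mean of at least 5 FPKM, and 2 rose and 1 fell without standard 3 and with the block and median-of-ratios scaling together. The block with median-of-ratios scaling gave 17 proximal tubule, 6 intercalated, 18 fatty acid oxidation, 17 oxidative phosphorylation and 12 gluconeogenesis genes falling, and 1 distal, 0 principal cell, 2 endothelial, 1 B cell, 1 purine and 6 cell death genes rising. With protein-coding genes only, 1 B cell and 4 neutrophil genes rose, and with pseudocount 0.1, 1 B cell gene.

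Leaving out 1 library at a time gave these lowest and highest counts. Falling genes ranged from 3 to 16 in the proximal tubule list, 0 to 5 in the thick ascending limb, 1 to 7 in intercalated cells, 0 to 12 in fatty acid oxidation, 0 to 18 in oxidative phosphorylation, 1 to 11 in gluconeogenesis, 0 to 4 in kidney hormones and 0 to 5 in the antioxidant list. Rising genes ranged from 0 to 2 in the distal list and in principal cells, 6 to 10 in podocytes, 1 to 4 in endothelium, 2 to 14 in T and NK cells, 0 to 1 in B cells, 2 to 4 in neutrophils, 10 to 17 in Toll-like receptors and in proliferation, 2 to 15 in interferon-stimulated genes, 2 to 4 in purine metabolism and 4 to 12 in cell death. In each of these lists the highest count came without adenine 3, alone or level with another library.

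The median of all tested genes went from 0.25 to -0.08 with quantile normalization. With median-of-ratios scaling, list medians changed sign for endothelium (0.20 to -0.10), principal cells (0.11 to -0.17) and purine metabolism (0.03 to -0.27). The same held for reference (0.06 to -0.23), sex-linked (0.11 to -0.18) and adipocyte genes (0.14 to -0.01). Among the 106 named genes, picked mainly from called genes, few directions reversed. Akr1b7, called upward in the report, went to -0.125 with quantile normalization. Ren1 went to a log2 change of -0.105 with median-of-ratios scaling, with and without the block, and Kdm5d to -0.056 with quantile normalization, neither being called before. Camera's direction reversed with quantile normalization for endothelium (adjusted p = 0.903), lymphatic vessel (0.903) and reference genes (0.325), with a mean of 5 FPKM for urothelium (0.919), and with block and median-of-ratios scaling for red blood cells (0.986). Fry, which asks whether a list moves one way and not whether it moves more than other genes, gave the opposite direction for endothelium (0.182), purine metabolism (0.0602), red blood cells (0.586) and reference genes (0.127). With 1 library left out the camera adjusted p ranged from 0.486 to 0.96 for endothelium, 0.204 to 0.999 for red blood cells and 0.334 to 0.999 for urothelium, with reversals without standard 1, standard 3 and adenine 3 in turn. Of 106 named genes, 81 kept their side of the threshold and their direction with quantile normalization, where 23 calls ended in the same direction and that of Akr1b7 in the opposite one, 89 with no filter, where 17 ended, and 93 with median-of-ratios scaling, where 12 ended. With 1 library left out 63 to 103 kept theirs, fewest without adenine 2. Count-based alternatives were not run, since the table holds no counts, and a comparison with authors' p-values was not run, since the table used has none.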

Other observations

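Tests of immune, podocyte and blood explanations below were chosen after the results were seen. Those on male-biased genes were set before their values were looked at, except for Kap and Cyp4a12a. Of the genes used there, Slc7a13, Slc22a30 and Cyp4a14 also belong to gene lists fixed at the start and described above. Grouping genes by the stem of their symbols gave 164 families of at least 10 tested genes, and camera called 30 of them, 14 higher and 16 lower (all with adjusted p = 0.896 with an estimated correlation). Of genes for subunits of mitochondrial complex I, 13 of 14 Ndufa and 9 of 10 Ndufb genes fell, with Ndufa1 from 495 ± 7.25 to 227 ± 27.6 FPKM and Ndufb4 from 119.5 ± 2.97 to 56.4 ± 7.67 FPKM (limma adjusted p = 0.00419 and 0.00405). Of cytochrome oxidase and assembly genes with the stem Cox 12 of 23 fell, and of mitochondrial ribosome genes 13 of 49 Mrpl and 8 of 29 Mrps genes, none rising. The medians of these 5 families were below 0 with median-of-ratios scaling and quantile normalization as well. Histone genes also fell, 6 of 14, and their median was -0.43, -0.63 with median-of-ratios scaling and -0.82 with quantile normalization. How far their levels follow cell division in these libraries was not tested.

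Matrix-degrading enzymes rose together, 13 of 14 Mmp genes and 9 of 12 Adamts genes, with Mmp2 from 2.51 ± 0.229 to 39.1 ± 16.7 FPKM, Mmp12 from 2.65 ± 1.15 to 37 ± 15.7 FPKM and Adamts4 from 0.737 ± 0.194 to 8.53 ± 2.77 FPKM (limma adjusted p = 0.00309, 0.00405 and 0.00402). Of 18 semaphorin (Sema) genes 13 rose, and of 10 genes with the stem Ms, most of them the membrane-spanning Ms4a group of leukocytes, 9 rose, Ms4a6d from 0.597 ± 0.296 to 12.6 ± 5.36 FPKM. The medians of these 4 families were above 0 with median-of-ratios scaling and quantile normalization as well. Fat-cell transcripts followed the replicate number and not the diet: Adipoq was 2.23, 3.03 and 0 FPKM in standard 1 to 3 and 2.39, 4.1 and 0 in adenine 1 to 3.

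Podocyte genes rose more than the pooled genes of other nephron segments and endothelium. A lower share of proximal tubule RNA alone would lift every other cell type alike. The podocyte median lay 0.90 ± 0.37 log2 units (SD, n = 3 adenine libraries) above the median of the other nephron and endothelial genes. That pooled median was -0.19, -0.15 and 0.04 in adenine 1 to 3. It includes the thick ascending limb, distal and intercalated lists, which camera placed below other genes. The gap therefore cannot exclude a lower proximal tubule share joined with falls in those lists. Scaling accounts for only part of the rise, since the podocyte median stayed 0.56 ± 0.24 above that of all tested genes. Immune and stromal cells that share some of these genes may add to the rise, which is left open here. A change in podocytes or in the glomerular share of the sampled tissue under the diet stays open as a hypothesis.

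B cell transcripts were high in 1 of the 3 adenine libraries. Ms4a1 and Ighm were 10.4 and 2432 FPKM in adenine 1 against 0.26 and 19.9 in adenine 2. The 222 immunoglobulin V genes summed to 45744, 1954 and 2830 FPKM in adenine 1 to 3 and to 2192, 565 and 224 in standard 1 to 3. The B cell list without Igj summed to 131, 8.99 and 9.73 FPKM in adenine 1 to 3 and to 10.8, 4.6 and 1.85 in standard 1 to 3. Both sums were highest in replicate 1 of each diet, and higher on the adenine-enriched diet at each replicate number. In adenine 1 the list stood 2.82 log2 units above the mean of the other 2 adenine libraries, T and NK cells 1.54 and macrophages 0.89. Blood left in the kidney may contribute, since adenine 1 also had the most haemoglobin, and its ratio of B cell to haemoglobin FPKM lay 1.25 SD above the mean of the other 5 libraries, inside the 2 SD set for blood but above 1 SD, which does not decide; that ratio was 0.943 in adenine 1 and 0.027 in standard 3. A piece of lymphoid tissue could bring Ccl21a as well, which was 0.98 times the mean of adenine 2 and 3, but its near-identical copies Ccl21b and Ccl21c are listed at 0 in all libraries, so shared reads keep this open. No biological explanation was tested, since the labels name no difference between these 3 samples.

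Kap and Cyp4a12a, both expressed more in male than in female mouse kidney, were lower on the adenine-enriched diet. Kap was 80709, 63908 and 69446 FPKM in standard 1 to 3 and 9474, 19688 and 31713 in adenine 1 to 3, which limma did not call (adjusted p = 0.336). It was called without the variance trend (0.018), with a robust variance prior (0.0178) and with a mean of at least 5 FPKM (0.0232), and adjusted p reached 0.897 over the other alternatives. Among 10 other male-biased genes 1 fell, Slc22a30, and 2 fell after median-of-ratios scaling, Slc7a13 and Slc22a30. Both Slc7a13 and Slc22a30 are also in the proximal tubule list. Of 4 female-biased genes Abcc3 and Prlr rose (limma adjusted p = 0.00752 and 0.0354), 1 of them after that scaling, Abcc3. The male-biased median lay -0.01 ± 0.36 from that of the proximal tubule list over the 3 adenine libraries, as a general loss of proximal tubule RNA would give. The lists share Slc7a13 and Slc22a30, so they are not independent and this closeness cannot decide for such a loss. Lower androgen-dependent transcription cannot be told apart from a general loss of proximal tubule RNA. The 4 female-biased genes lay 2.31 ± 1.16 above the male-biased ones, just under 2 SD. The male-biased median was -1.76, -1.17 and 0.01 in adenine 1, 2 and 3, against -1.54, -0.96 and -0.39 for the proximal tubule list. It lay lower than that list in adenine 1 and 2 and higher in adenine 3, so the small mean difference joins gaps of opposite sign.

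The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The diets gave 5637 changed genes and 1729 changed at least 2-fold, and the highest other split gave 2 and 2, so that 1 of 10 splits reached each count. For gene lists, 3 of 10 splits reached the 22 camera calls of the diets, the highest with 24, and splits that mix the diets gave 7 to 24. Each mixed split holds samples of both diets in each group. Part of the diet difference therefore stays in its contrast and the rest enters the spread within its groups. The gene and list counts of mixed splits thus cannot show what samples without a diet difference would give, and no conclusion is drawn from them. The replicate numbers were taken to pair the samples, though no label states it. If they do, then of the 4 splits that part all 3 pairs the other 3 gave 1, 0 and 1 changed genes and 24, 12 and 8 lists.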
